A study of Mus musculus with 7 samples.

How the data were processed

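Cells of whole mouse hearts were profiled by droplet-based single-cell RNA sequencing (10x Genomics) at embryonic days 12.5, 13.5, 14.5 and 15.5, in 7 libraries. Each stage had a library with replicate number 1, and E13.5, E14.5 and E15.5 also had a library with replicate number 2. The replicate 1 libraries are called the first set and the replicate 2 libraries the later set, because the labels of the replicate 2 libraries lack the mouse strain (ICR) and their files have another format. Per the labels, the authors made the values with Cell Ranger 3.1.0 on mm10, and the deposited values are counts of unique molecular identifiers (UMIs) per gene and barcode, with no normalization. The headers of the later-set files name Cell Ranger 4 instead. The first set was deposited as barcodes already called as cells by an unstated rule, with 27998 genes and an eGFP entry. The later set was deposited with all barcodes and 32285 genes, no eGFP entry among them. The 27040 genes shared by identifier were kept, of which 1227 had another symbol in the first set, and the later symbols were used. They held 99.5% to 99.6% of the UMIs of each library. Coordinates came from GENCODE vM21 (mm10) for 26963 of these genes.

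Cells of the later set were called where the UMI total reached 1/10 of the 99th percentile of the 5000 highest barcodes, which gave thresholds of 3067, 3399 and 3012 UMIs at E13.5, E14.5 and E15.5. The lowest deposited cell of the first set had 3393 UMIs. Cells with fewer than 1000 UMIs or over 25% mitochondrial UMIs were removed. Scrublet scored doublets in each library; its automatic threshold marked between 0.0642% and 1.92% of cells, so the highest-scoring cells were removed up to an expected rate of 0.8% per 1000 cells, a choice made after seeing the data. This removed 3.08% to 6.28% of cells per library.

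Counts were scaled to 10000 per cell and log-transformed. The 2000 most variable genes were centred within each library, reduced to 30 principal components and clustered with the Leiden method (resolution 1, 20 neighbours). Mitochondrial, ribosomal protein, haemoglobin, histone and sex-specific genes were left out of the clustering. So were the members of the 4 lists compared between classes, which cover epithelial- or endothelial-to-mesenchymal transition regulators (EndMT regulators), mesenchymal effectors, S phase, and G2 and M phase. Genes correlated with a cell cycle list above 0.15 were left out too, a rule set after seeing the data. Clusters were named from marker lists, and endothelial-like cells were clustered and named again. A cluster took a name with a mean marker log2 ratio of at least 0.25 or at least 3 own markers among its top 10 genes. It stayed unnamed otherwise, or when fewer than 3 of its markers were detected, when another class had more markers among its top 10 genes, or when an endothelial-like cluster scored highest for another cell type. These limits were set after seeing the data. Under them cluster 15 of the endothelial-like cells, which scored highest for coronary vascular markers (1.39), stayed unnamed because it had 0 of these and 2 of another class among its top 10 genes. Fabp4, Cd36, Gpihbp1, Rgcc, Aplnr and Esm1 served to name the coronary-vascular-like class, and Npr3, Cdh11, Nfatc1, Nrg1 and Tmem108 the endocardial-like class, so their levels are not independent of the class names. No projection, trajectory or lineage call was made.

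The library was the replicate. Counts were summed per library and class with at least 20 cells, filtered with edgeR's filterByExpr (minimum count 10) and normalised with TMM factors. Genes were fitted with edgeR's robust quasi-likelihood model with embryonic day as a numeric term and set as a second term. The slope is therefore a log2 change per day, given with its standard error (SE) from 7 libraries. The difference between class slopes came from a joint fit with a term per library for the shared part and a class-by-day term. The endocardial-like and coronary-vascular-like sums of the same libraries were compared with library as a term. Adjusted p-values are Benjamini-Hochberg values, and genes with adjusted p under 0.05 were called. The 29 gene lists were tested against all other genes with limma's camera (preset correlation 0.01), with an estimated correlation as an alternative. For cell shares, the slope of the logit share (0.5 added to each count) on day with set as a term was tested by an exact two-sided permutation of stages within sets. Its 144 orders allow no p below 0.0139. The share of cells with an EndMT regulator UMI was counted after thinning each cell to 3000 UMIs. Intervals of single shares are exact 95% Clopper-Pearson intervals, and intervals and limits for a count of 0 (3 counts) cover counting error only. The labels do not say whether libraries came from separate animals, so p-values measure only the spread between these libraries.

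The groups, model, lists, cell markers, main limits and alternatives were set before the data were examined, except where stated. Named genes were the 10 rising and 10 falling genes per class with the largest slope among called genes with mean log2 CPM (UMI counts scaled by edgeR to the library size) of at least 5 and slopes of the same sign in both sets. Mitochondrial, ribosomal protein, haemoglobin, X-inactivation and Y-linked genes and unnamed gene models were left out. For each list, the 2 to 4 members with the smallest p were named. For the slope difference, 5 genes per direction were named. For the comparison of classes, 4 members per list and direction were named. Members outside this rule were named after their values were seen: the EndMT regulators of the endocardial-like class that did not pass, all EndMT regulators in the comparison of classes, the regulators whose shares of cells are given singly, and list members or list genes whose slope difference is given for comparison.

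Simulated counts, with an added change for some genes, were used to test the fits. A change of 0.5 log2 per day was recovered for 83.8% of genes in the endocardial-like and 86.9% in the coronary-vascular-like class, and for 65% in the test of the slope difference. Genes with no added change were called at 0.0728%, 0.158% and 0.0371%. These rates are for simulated counts and need not hold for the real ones, whose calls changed with the set term and single libraries. A raised list was called and 0 of 20 unchanged lists were. Genes were drawn independently there, so this does not test the preset correlation of 0.01 on lists whose members move together. The S phase list of endocardial-like cells, for 1, had an estimated correlation of 0.518. By exact p under 0.05, not adjusted over classes, the permutation test called 3.5% of 200 simulated shares with no slope and 97.5% with a logit slope of 0.5. These rates do not hold for calls adjusted over classes, where a lone slope at the smallest p cannot pass. Alternatives covered doublets, mitochondrial limit, cell calling, clustering, set term, gene filter, DESeq2, stage as a factor and each library left out. Added after seeing the data were an Xist term, gene and list fits within sets, edgeR without TMM factors and the fits without both E12.5 replicate 1 and E15.5 replicate 1. Versions were R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, Python 3.11.15, scanpy 1.11.5, leidenalg 0.10.2, python-igraph 0.11.9, scikit-learn 1.9.0, scipy 1.17.1, numpy 2.4.6 and statsmodels 0.14.6.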

Results

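The transcriptomes of single cells from whole mouse hearts were measured at 4 stages a day apart, from E12.5 to E15.5, when the ventricular wall matures and the coronary vessels spread. The first set held 1 library per stage and the later set 1 library each at E13.5, E14.5 and E15.5. The total UMI counts of the first set were 73726853 at E12.5, 77033915 at E13.5, 61824046 at E14.5 and 67375110 at E15.5. Those of the later set were 98160440, 113791161 and 77097216 at E13.5, E14.5 and E15.5. After filtering, 36680 cells were kept. They numbered 5604, 4860, 3744 and 4501 in the first set, by stage, and 5669, 7358 and 4944 in the later set. Median UMIs per cell lay between 9011 and 15053, and median detected genes between 2624 and 3466. The median mitochondrial share of UMIs was 10.6% at E15.5 in the first set and between 2.98% and 6.26% in the other libraries.

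To describe how the cells of the heart were composed as it grew, cell classes were compared by stage. Endothelial-like cells, which carry Pecam1, Cdh5 and Kdr, made up 18.7% of cells at E12.5. In the first set they made up 15.6%, 14.4% and 10.3% at the 3 following stages, and in the later set 16.3%, 17.2% and 16.7%. Cushion mesenchymal-like cells, which form the valve primordia, made up 19.5% at E12.5, 13.9% and 15.4% at E13.5 and 8.12% and 6.90% at E14.5. At E15.5 cushion mesenchymal-like cells made up 1.96% in the first set and 8.52% in the later set, the latter above the 6.90% of the later set at E14.5. Fibroblast-like cells made up 3.91% at E12.5 and 7.42% and 14.8% in the libraries of E15.5. Cardiomyocyte-like cells made up 25.6% at E12.5, and 59.1% and 27.8% at E15.5.

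Slopes of these shares were tested by exact permutation within sets, and no class passed after correction over the classes. With 144 orders, a single class could not pass this correction even at the smallest p, so not passing does not argue against a slope. The logit slope was −0.152 ± 0.0575 per day (SE, n = 7; exact p = 0.0556, adjusted p = 0.167) for endothelial-like cells. Within sets it was −0.217 in the first and 0.0121 in the later, so the pooled value did not hold in both, and with a mitochondrial limit of 10% the slope over 7 libraries was 0.0165. It was −0.672 ± 0.174 (exact p = 0.0278, adjusted p = 0.125) for cushion mesenchymal-like and 0.286 ± 0.0759 (exact p = 0.0278, adjusted p = 0.125) for fibroblast-like cells. Exact p-values for cardiomyocyte-like, epicardial-like, erythroid-like and leukocyte-like cells were 0.167, 0.181, 0.306 and 0.569.

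The series asks how endocardial cells of the ventricle give rise to trabecular vessels, so the endothelial-like cells were divided again. Coronary-vascular-like cells, named from Fabp4, Aplnr, Cd36 and other vessel markers, made up 6.50% of endothelial-like cells at E12.5 (68 of 1046 cells; 95% exact interval 5.08% to 8.17%). They made up 9.75% and 9.83% at E13.5, 13.1% and 12.1% at E14.5, and 24.0% and 23.5% at E15.5. In both sets the share was higher at each later stage. Within the class, cluster 4 (Kcne3, Igfbp3, Adm and Esm1, the last an endothelial tip cell gene) held 59 of 68 cells at E12.5. Cluster 8 (Rgcc, Aplnr, Gpihbp1 and Cd36, genes of capillary endothelium) held 77 of 111 and 125 of 194 cells at E15.5. Valve endocardial-like cells, with Wnt4, Wnt9b and Cldn11, made up 210 of 1046, 94 of 759, 57 of 541 and 12 of 463 endothelial-like cells of the first set by stage, and 239 of 926, 93 of 1262 and 91 of 824 of the later set. Endocardial-like cells, with Npr3, Nfatc1 and Nrg1, made up between 44.5% and 62.2% in the 7 libraries.

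The odds ratio per day of the coronary-vascular-like class was 1.64 (logit slope 0.495 ± 0.0565, SE, n = 7). The exact permutation p was 0.0139, the smallest the design allows, and the adjusted p over 6 endothelial classes was 0.0833, so the slope did not pass after correction. Over 6 classes a slope at that smallest p passes only if other classes have low p-values too, so the correction cannot decide here. Within sets the slope was 0.486 in the first and 0.518 in the later. The exact p was 0.0417 (adjusted p = 0.0833) for the valve endocardial-like slope of −0.633 ± 0.188 and 0.0278 (adjusted p = 0.0833) for the unnamed cells' slope of −0.118 ± 0.023. Endocardial-like cells had a slope of 0.035 ± 0.119 (exact p = 0.806). Exact p-values for large-artery-like and venous-like cells were 0.5 and 0.264.

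**Figure D1:**
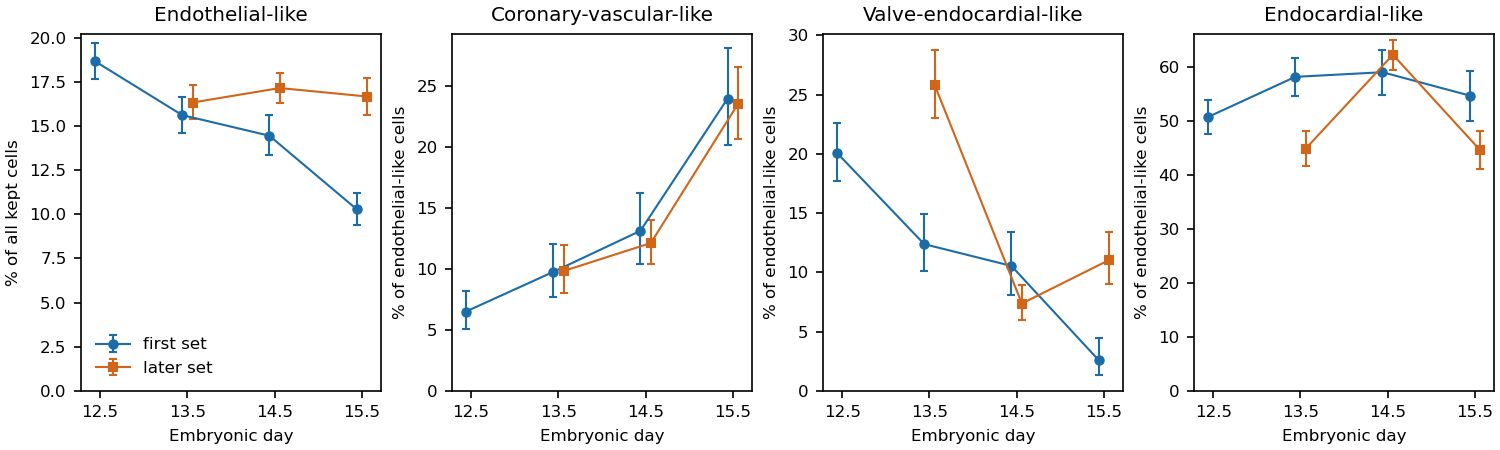
Share of cells in percent by embryonic day, with exact 95% intervals, for endothelial-like cells among all cells and for 3 classes among endothelial-like cells; symbols mark the first and later sets. Coronary-vascular-like cells go from 6.50% at E12.5 to 24.0% and 23.5% at E15.5.

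Within endocardial-like cells, Hapln1 and Hmga2 fell the most with stage among the named genes, while Fbln2 and Fabp4 were among those that rose. Hapln1, which links hyaluronan to proteoglycans in the cardiac jelly, fell by 1.49 log2 per day (SE 0.21, n = 7; edgeR quasi-likelihood adjusted p = 0.0212; ENSMUSG00000021613, chr13:89539796-89611652). Its level was 166 CPM at E12.5 and 2.15 and 19.8 CPM at E15.5. Hapln1 fell in coronary-vascular-like cells too, with no slope difference called, so its fall was not particular to this class. It was also a marker used to name cushion mesenchymal-like cells, and free RNA from those cells was not tested for it. Hapln1 was among the top 10 genes of cluster 3, which was named valve endocardial-like. Its level may therefore not be independent of how endocardial-like cells were divided from valve endocardial-like cells, which was not tested. Hmga2, a chromatin protein of fetal growth and a regulator in the EndMT list, fell by 0.90 (SE 0.16, adjusted p = 0.0237; ENSMUSG00000056758, chr10:120361275-120476469). Fbln2, an elastic-fibre protein of the mesenchymal effector list, rose by 0.90 (SE 0.07, adjusted p = 2.87e-05; ENSMUSG00000064080, chr6:91212455-91272540).

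Of 11370 genes tested, 912 changed with stage, 550 upward and 362 downward. Among the genes that met the naming limits, which include a mean log2 CPM of at least 5, the largest rises and falls were as follows. Col6a3, Mgp and Mfap5, all matrix proteins, rose by 1.20, 1.17 and 0.68 log2 per day. Fabp4, a fatty acid carrier, rose by 1.31 (SE 0.07, adjusted p = 4.24e-07), and G0s2, an inhibitor of lipolysis, by 0.80. Edn1, the vasoconstrictor endothelin-1, rose by 0.68 and Tmem158 by 0.94. Ckm and Mb, the creatine kinase and myoglobin of muscle, rose by 1.68 and 0.90. Besides Hapln1 and Hmga2, the falls under these limits were those of Nnat (−0.81), Col26a1 (−0.80), Cd24a (−0.62), Skp2 (−0.50), Sox11 (−0.47), Igf2bp1 (−0.47), Fbn2 (−0.46) and Fdps (−0.45). Skp2 drives degradation of cell cycle inhibitors, Igf2bp1 binds fetal growth mRNAs and Fdps makes isoprenoids. These 20 genes had slopes of the same sign in both sets, as the rule for naming them required.

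Groups fixed in advance were then tested as lists. In the S phase list, which had the smallest p with the preset correlation, 16 of 27 members fell and none rose (24 fell when adjusted over the list alone), with a median slope of −0.29 (camera adjusted p = 3.84e-18; adjusted p = 0.207 with an estimated correlation). Gins2, Dut, Nasp and Dtl, all of DNA replication, fell by 0.38, 0.33, 0.34 and 0.34 log2 per day. In fits of other classes, chosen after the data were seen, the S phase list fell too. Camera adjusted p-values were 5.8e-07 in valve endocardial-like, 2.66e-07 in cardiomyocyte-like and 0.00108 in fibroblast-like cells. They were 0.00172 in epicardial-like, 9.34e-06 in cushion mesenchymal-like and 7.90e-13 in leukocyte-like cells. With an estimated correlation they lay between 0.313 and 0.56. The fall in endocardial-like cells was therefore not particular to them. For the G2 and M phase list, no member of 31 passed alone or adjusted over the list alone, while the list had a median of −0.26 (adjusted p = 1.35e-08; adjusted p = 0.427 with an estimated correlation), a call that ended without E15.5 replicate 1. The EndMT regulator list also fell (adjusted p = 0.0175; adjusted p = 0.207 with an estimated correlation; median −0.16), with 3 of 12 members down and 1 up (5 and 1 adjusted over the list alone). Hmga2, Prrx2 (−0.63) and Foxc2 (−0.31) fell and Tcf4 (0.27) rose. The transcription factors that define the transition did not pass: Snai1 had a slope of −0.18, Snai2 of −0.08, Twist1 of −0.16, Zeb1 of 0.02 and Zeb2 of 0.02. The call on the EndMT regulators ended without E12.5 replicate 1, with stage as a factor, with an Xist term and in the later set alone. In the fits of other classes the list also fell in cardiomyocyte-like (camera adjusted p = 0.00355), epicardial-like (0.00981) and valve endocardial-like cells (0.0161). With an estimated correlation these values were 0.482, 0.28 and 0.406. It was not called in cushion mesenchymal-like, fibroblast-like and leukocyte-like cells. Prrx2 fell by 0.61 in cardiomyocyte-like cells, and free RNA was not tested as a source of its fall in endocardial-like cells. The mesenchymal effectors were not called (adjusted p = 0.153), with 4 of 21 members up and 1 down (6 and 2 adjusted over the list alone); Fbln2, Col5a1 (0.47) and Sparc (0.28) rose and Tagln (−0.66) fell.

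In the flow-responsive list of the endocardial-like class 6 of 12 members rose and none fell (7 adjusted over the list alone, median 0.33; adjusted p = 1.00e-06, and 0.207 with an estimated correlation), among them Txnip (0.44), Heg1 (0.37), Pi16 (0.71) and Edn1. The basement membrane and matrix list had 8 of 20 members up and 1 down (10 and 1 adjusted over the list alone, adjusted p = 6.62e-05, and 0.35 with an estimated correlation). Timp3 (0.54), Lama4 (0.32), Col15a1 (0.83) and Lox (0.85) rose. The markers of fibroblasts rose beside this matrix group, with 3 of 10 members up (4 adjusted over the list alone, adjusted p = 0.00877, and 0.427 with an estimated correlation), among them Col6a2 (0.75), Col6a1 (0.68) and Dcn (0.84), which the mesenchymal effector list also holds. That call ended in the first set alone, without E13.5 replicate 2, without E15.5 replicate 2 and without the set term, which also ended the calls on the matrix, TGF-beta, endocardial and cardiomyocyte lists of this class. The venous and capillary list had 3 of 11 members up (5 up and 1 down adjusted over the list alone, adjusted p = 0.000196, and 0.207 with an estimated correlation), led by Fabp4, Gpihbp1 (0.83) and Cd36 (1.20), which bind and take up lipids. The fatty acid list, which shares Fabp4, Cd36 and Gpihbp1 with it, had 4 of 18 up (5 adjusted over the list alone, adjusted p = 0.00285, and 0.207 with an estimated correlation), with Fabp5 at 0.37. In fits of other classes, chosen after the data were seen, the venous list rose too. Adjusted p was 0.000133 in fibroblast-like, 0.0149 in cushion mesenchymal-like, 0.0325 in cardiomyocyte-like and 0.041 in valve endocardial-like cells. With an estimated correlation it was 0.128 to 0.56. The list was not called in epicardial-like and leukocyte-like cells. Fabp4 rose by 1.63 in fibroblast-like cells, and free vessel RNA was not tested as its source in endocardial-like cells.

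The tip cell and sprouting list rose with 5 of 16 members (6 adjusted over the list alone, adjusted p = 0.00486, and 0.207 with an estimated correlation), with Robo4 (0.60), Plaur (0.74), Mcam (0.36) and Angpt2 (0.70). The BMP list had 5 of 17 up (7 adjusted over the list alone, adjusted p = 0.0015, and 0.407 with an estimated correlation), with Eng (0.26), Tmem100 (0.26), Acvrl1 (0.51) and Id2 (0.21). The TGF-beta list had 4 of 18 up (8 up and 1 down adjusted over the list alone, adjusted p = 0.00461, and 0.207 with an estimated correlation), with Ltbp4 (0.42), Tgfbr2 (0.30), Ltbp3 (0.45) and Ski (0.23). The junction and identity list had 2 of 20 up, Egfl7 (0.21) and Jam2 (0.54) (11 up and 1 down adjusted over the list alone, adjusted p = 0.00179, and 0.207 with an estimated correlation). The list of endocardial genes had 5 of 14 up and 1 down (8 and 1 adjusted over the list alone, adjusted p = 0.00179, and 0.272 with an estimated correlation), with Tmem108 (0.32) and Smoc1 (0.35) up and Gata5 (−0.48) down. The calls on the endocardial and BMP lists ended without centring. The antigen presentation and interferon list had 4 of 15 up (7 adjusted over the list alone, adjusted p = 0.000801, and 0.272 with an estimated correlation), with Ifi27 (0.27), Ifitm3 (0.32), Bst2 (0.25) and Tapbp (0.33).

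Markers of cardiomyocytes moved with the same stages. In endocardial-like cells 6 of 13 rose (8 up and 1 down adjusted over the list alone, median 0.29; adjusted p = 0.000279, and 0.207 with an estimated correlation), among them Myh7 (0.47), Tnnt2 (0.39), Ryr2 (0.56) and Tnni3 (0.42). Lists with no call in this class were Notch (adjusted p = 0.372), arterial (0.675; Gja4 fell by 0.28), VEGF signalling (0.793; Dusp5 fell by 0.61 and Nr4a1 by 0.51; its median slope was 0.05 and its mean −0.04), Wnt signalling (0.379; Wnt2 rose by 0.76 and Fzd6 by 0.41, Wnt5a fell by 0.48), cyclin inhibitors (0.366; Cdkn1c fell by 0.26), glycolysis (0.793), oxidative phosphorylation (0.954), immediate early genes (0.793) and fetal growth genes (0.123; Peg3 rose by 0.28). Adjusted over the list alone, no arterial, Notch, glycolysis or oxidative phosphorylation gene passed; 2 VEGF genes and 1 immediate early gene fell, 2 Wnt genes rose and 1 fell, 1 cyclin inhibitor rose and 1 fell, and 4 fetal growth genes rose and 4 fell. Lists for epicardial, mural, erythroid and leukocyte markers were not called either (adjusted p = 0.353, 0.227, 0.857 and 0.379; the erythroid list had a median of 0.31 and a mean of −0.15).

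With edgeR, the count of 912 was 690 in the first set alone, of which 564 were among the 912, and 109 in the later set alone. It was 227 without E12.5 replicate 1, 191 without E15.5 replicate 1, 542 without E13.5 replicate 2, 235 without centring, 61 without the set term, 346 with stage as a factor and 164 with an Xist term. Cluster 1 (Pla2g7, Ptn, Dlk1) held 270 of 530 endocardial-like cells at E12.5 and 17 of 253 at E15.5 in the first set, and cluster 2 (Enpp6, G0s2, Mal) held 35 and 103. In the later set cluster 1 held 144 of 415, 240 of 785 and 124 of 367 endocardial-like cells by stage, and cluster 2 held 35, 141 and 66. Inside clusters 0, 2 and 5, fitted after the data were seen, 240 of 9785, 109 of 6434 and 74 of 8382 genes were called. These fits held fewer cells than the whole class. Clusters 1 and 11 were not fitted, so a change inside them was not tested. Hapln1 fell by 1.42, 1.72 and 1.42 log2 per day inside clusters 0, 2 and 5 (edgeR adjusted p = 0.0449, 9.93e-05 and 5.29e-05). The S phase list fell in each of the 3 (adjusted p = 5.84e-10, 3.21e-12 and 9.80e-09, and 0.308, 0.177 and 0.537 with an estimated correlation), while the G2 and M phase list fell in clusters 0 and 2 (5.84e-10 and 1.98e-06, and 0.37 and 0.329 with an estimated correlation) and was not called in cluster 5 (0.871). Sex differed by library too: Xist had 1 and 9 UMIs at E14.5 and E15.5 in the first set and at least 15862 in each other library. The Y-linked gene Ddx3y had 1543 and 1654 UMIs at E12.5 and E13.5 in the first set. It had 719 and 1126 at E13.5 and E15.5 in the later set, so these libraries held RNA of both sexes.

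**Figure D2:**
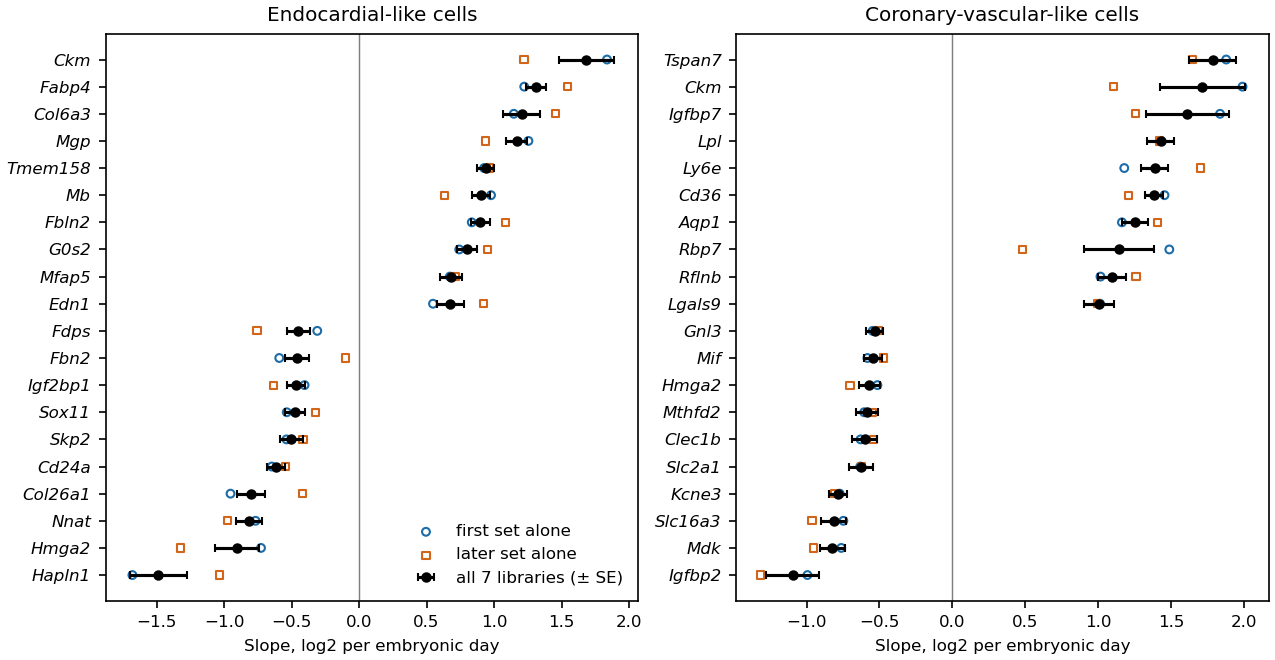
Log2 change per day with its standard error for the 20 named genes of each class, with the slopes of the first and later sets drawn beside each. Ckm (1.68) and Hapln1 (−1.49) bound the endocardial-like genes, and Tspan7 (1.79) and Igfbp2 (−1.10) the coronary-vascular-like genes.

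In the coronary-vascular-like class, the lipid uptake genes Cd36 and Lpl rose with stage while Slc2a1 and Slc16a3, which carry glucose and lactate, fell. Cd36, the fatty acid transporter of capillaries, rose by 1.38 log2 per day (SE 0.06, n = 7; edgeR adjusted p = 2.17e-11; ENSMUSG00000002944, chr5:17781690-17888801). It stood at 25.8 CPM at E12.5 and at 617 and 368 CPM at E15.5. Lpl, the lipoprotein lipase of muscle and fat, rose by 1.43 (SE 0.10, adjusted p = 1.44e-08), and Aqp1, a water channel, by 1.25. Kcne3, a potassium channel subunit of the tip cell list, fell by 0.78 (SE 0.06, adjusted p = 1.78e-07; ENSMUSG00000035165, chr7:100176502-100184869). The slopes of Slc2a1 and Slc16a3 were −0.63 and −0.81. Cd36 and Fabp4 also served to name the class.

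Of 9285 genes tested, 1436 changed, 713 upward and 723 downward. The largest rise among genes that met the naming limits, a mean log2 CPM of at least 5 among them, was that of Tspan7, a tetraspanin, at 1.79 (SE 0.16, adjusted p = 4.01e-05; ENSMUSG00000058254, chrX:10485158-10596605). Igfbp7 (1.61), Ly6e (1.39), Rbp7 (1.15), Rflnb (1.09) and Lgals9 (1.01) followed, with the muscle gene Ckm at 1.72 (SE 0.29, adjusted p = 0.0219). Falling genes were Igfbp2 (−1.10), Mdk (−0.82), Clec1b (−0.60), Mthfd2 (−0.59), Hmga2 (−0.57), Mif (−0.55) and Gnl3 (−0.53). Igfbp2 and Mdk bind or act as growth factors, Mthfd2 serves folate metabolism and Gnl3 is a nucleolar protein of dividing cells.

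Among the lists, 13 of 19 glycolysis genes fell and none rose (14 adjusted over the list alone), with a median of −0.30 (camera adjusted p = 2.34e-09; adjusted p = 0.303 with an estimated correlation). Pgam1 fell by 0.41 and Tpi1 by 0.33. The fatty acid list rose with 7 of 15 members (8 adjusted over the list alone, adjusted p = 5.16e-07, and 0.288 with an estimated correlation). Of the venous and capillary list 9 of 12 rose (11 adjusted over the list alone, median 0.46; adjusted p = 1.35e-13, and 0.0461 with an estimated correlation), including Gpihbp1 (0.99), the capillary anchor of lipoprotein lipase, and Fabp4 (0.84). The flow-responsive list rose with 6 of 10 (7 adjusted over the list alone, median 0.63; adjusted p = 4.38e-09, and 0.0461 with an estimated correlation). Its members Klf2 (0.83) and Klf4 (0.82), transcription factors induced by laminar shear and also early response genes, and Txnip (0.76) rose. Of the antigen presentation and interferon list 9 of 13 rose (11 adjusted over the list alone, median 0.54; adjusted p = 2.34e-09, and 0.0461 with an estimated correlation), with Ly6c1 (1.98), Ifitm3 (0.54) and Bst2 (0.46). The antigen presentation and interferon list also rose in leukocyte-like (adjusted p = 1.39e-08), epicardial-like (2.15e-05) and cushion mesenchymal-like cells (0.0001965). It rose in fibroblast-like (0.000216) and valve endocardial-like cells (0.0163) too, and was not called in cardiomyocyte-like cells (0.356). With an estimated correlation these rises had values of 0.128 to 0.491. These fits were chosen after the data were seen. In coronary-vascular-like cells 10 of 19 members of the junction and identity list rose (14 adjusted over the list alone, adjusted p = 1.66e-07, and 0.0461 with an estimated correlation), with Jam2 (1.56), Egfl7 (0.27), Fli1 (0.25) and Cldn5 (0.26). These 4 lists, venous and capillary, flow, antigen and junction, were the ones called with an estimated correlation. None of them was called so when any single library was left out, with stricter cell calls, stage as a factor or an Xist term, or in either set alone. Among the venous and capillary genes that rose, Aplnr, Fabp4, Cd36, Rgcc and Gpihbp1 also served to name the class. The rise of that list is therefore not independent of how the class was defined.

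The immediate early list rose with 8 of 16 members and 1 down (9 and 2 adjusted over the list alone, adjusted p = 4.07e-06, and 0.288 with an estimated correlation), with Dusp1 (0.46), Zfp36 (0.69) and Nr4a1 (0.56) up and Hsp90aa1 (−0.34) down. The same list rose in cushion mesenchymal-like (adjusted p = 7.93e-16, and 0.307 with an estimated correlation), leukocyte-like (2.57e-06, and 0.312) and fibroblast-like cells (0.000133, and 0.413), in fits chosen after the data were seen. It was not called in valve endocardial-like (0.247), epicardial-like (0.138) and cardiomyocyte-like cells (0.533). The BMP list rose with 4 of 14 (4 adjusted over the list alone, adjusted p = 0.000417, and 0.477 with an estimated correlation), with Eng (0.27), Id1 (0.29), Bmp4 (0.65) and Id3 (0.15). The basement membrane list had 9 of 19 up and 1 down (12 and 2 adjusted over the list alone, adjusted p = 0.00268, and 0.477 with an estimated correlation), with Col4a2 (0.26) and Adamts9 (0.36) up and Hapln1 (−1.28) down, a call that ended without the set term. The cyclin inhibitors rose with 5 of 9 (5 adjusted over the list alone, adjusted p = 0.00522, and 0.477 with an estimated correlation), with Cdkn2c (0.74), Btg1 (0.22), Cdkn2d (0.33) and Ccng2 (0.39). That call ended without E12.5 replicate 1, without E15.5 replicate 1, with stage as a factor, with an Xist term and in the later set alone. Markers of cardiomyocytes rose here as well, with 6 of 13 up (8 adjusted over the list alone, median 0.45; adjusted p = 6.87e-05, and 0.477 with an estimated correlation), among them Tnnc1 (0.36), Tnni3 (0.53), Ttn (0.55) and Myl3 (0.51), a call that ended without the set term and in the later set alone.

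The EndMT regulators were not called in this class (adjusted p = 0.835; median 0.08, mean −0.02), with 2 of 10 up and 2 down (2 and 2 adjusted over the list alone). Snai2, a repressor of junction genes, rose by 0.75 (SE 0.13, edgeR adjusted p = 0.000581) and Tcf4 by 0.33, while Foxc2 fell by 0.74 and Hmga2 by 0.57. The mesenchymal effectors had 2 of 17 up and 2 down (2 and 2 adjusted over the list alone, adjusted p = 0.935; median 0.10, mean −0.03), with Sparc (0.31) and Vim (0.19) up and Lum (−0.81) and Tagln (−0.75) down. Other lists without a call were S phase (adjusted p = 0.143; Rrm2 fell by 0.21 and Dut by 0.17), G2 and M phase (0.33; Nusap1 rose by 0.33, Bub1 fell by 0.27 and Ube2c by 0.16), tip cell (0.716; Nrp1 rose by 0.24 and Nid2 by 0.22, Flt4 fell by 0.31; inside cluster 4, fitted after the data were seen, the list rose with an adjusted p of 0.0166, and 0.36 with an estimated correlation), arterial (0.923; Sox17 rose by 0.18; median −0.04, mean 0.01), Notch (0.481; Lfng rose by 0.85 and Mfng fell by 0.16) and TGF-beta signalling (0.46; Tgfbr2 rose by 0.37 and Ltbp1 by 0.94, and Tgfbi fell by 0.60). The VEGF list (0.159; Nr4a1 and Nrp1 rose and Flt4 fell), Wnt (0.733), endocardial genes (0.231; Adamts1 rose by 0.24), oxidative phosphorylation (0.733; Cox7b fell by 0.17) and fetal growth genes (0.341; Meg3 fell by 0.57, Igf2bp1 by 0.39 and Igf2bp2 by 0.29) were not called. Nor were the markers of fibroblasts (0.733; median 0.03, mean −0.07), epicardium (0.801), mural cells (0.855; median −0.01, mean 0.01), erythroid cells (0.557; median 0.13, mean −0.44) and leukocytes (0.557). Adjusted over the list alone, 2 S phase genes fell, 1 G2 and M phase gene rose, 4 tip cell genes rose and 3 fell, 1 Notch gene rose and 1 fell, 4 TGF-beta genes rose and 3 fell, 3 VEGF genes rose and 1 fell, 1 endocardial gene rose, 5 fetal growth genes rose and 4 fell, and 1 fibroblast gene fell. No arterial, Wnt or oxidative phosphorylation gene passed by that count.

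With edgeR, the coronary-vascular-like count of 1436 was 1083 in the first set alone, with 943 of the 1436 among them, and 383 in the later set alone. It was 647 without E12.5 replicate 1, 451 without E15.5 replicate 1, 565 without the set term, 866 by DESeq2, 784 with stage as a factor and 632 with an Xist term. E15.5 replicate 1 also held 238 cells with lung epithelial markers, and Sftpc RNA, a lung surfactant gene, was at 76.4 to 91.0 CPM across the classes measured.

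**Figure D3:**
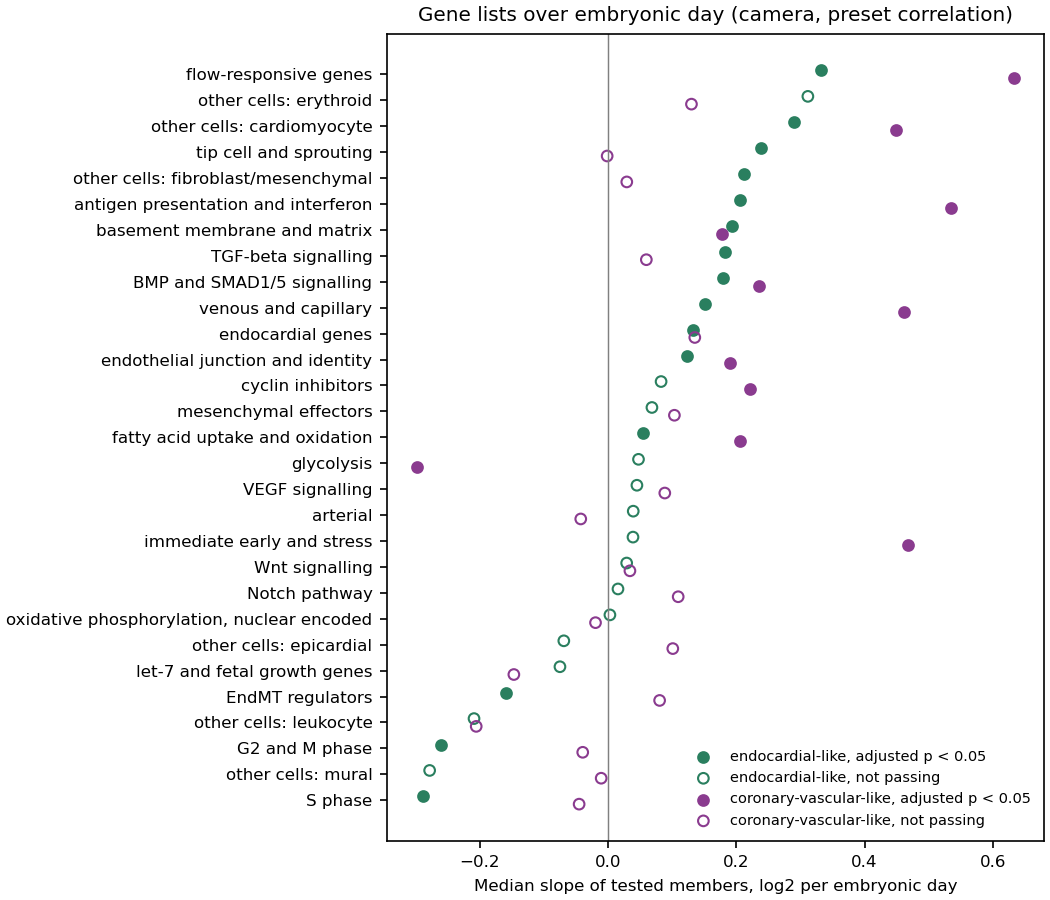
Median log2 change per day of the tested members of each gene list in endocardial-like and coronary-vascular-like cells; filled symbols mark an adjusted p under 0.05 with the preset correlation. S phase (−0.29) is low in endocardial-like cells, and flow-responsive genes (0.63) are high and glycolysis (−0.30) low in coronary-vascular-like cells.

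To ask where the vessel-like cells parted from the endocardium with time, the slopes of the classes were compared directly. Tspan7, Ly6e and Lgals9, genes of membrane and immune-related proteins, had a higher slope in the coronary-vascular-like class, by 1.66 (SE 0.19), 1.19 (SE 0.12) and 1.07 (SE 0.09) log2 per day. Their slopes in endocardial-like cells were 0.05, 0.19 and 0.01. Timp2, an inhibitor of matrix proteases, and Rgcc, a cell cycle regulator and class marker, differed by 0.85 and 0.83. Npr3, the natriuretic peptide clearance receptor and an endocardial marker, had a lower slope in coronary-vascular-like cells, by 1.10 (SE 0.21; ENSMUSG00000022206, chr15:11839896-11907287). Egln3 and Igfbp3, both induced by hypoxia, were lower by 0.91 and 0.91, Pdgfb, which recruits mural cells, by 0.85 and Sat1, a polyamine enzyme, by 0.76. Egln3 had slopes of 0.59 in endocardial-like and −0.31 in coronary-vascular-like cells, Igfbp3 of 0.38 and −0.39, and Pdgfb of 0.89 and 0.04.

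The joint edgeR fit of 7 libraries per class called 443 of 11264 genes, 205 with a higher and 238 with a lower slope in coronary-vascular-like cells. Adjusted p-values for the 10 named genes lay between 5.76e-09 for Lgals9 and 0.0262 for Rgcc. Snai2 had a higher slope in coronary-vascular-like cells (0.78, adjusted p = 0.0176), as did Klf2 (0.75, adjusted p = 0.0344) and Nr4a1 (0.99, adjusted p = 0.000244), while that of the glycolytic gene Pgam1 was lower (−0.37, adjusted p = 0.00207). The Snai2 difference rests on UMIs in few cells. No difference was called for Hmga2 (0.26, adjusted p = 0.374), Foxc2 (−0.34, adjusted p = 0.154), Hapln1 (0.12, adjusted p = 0.721), Slc2a1 (−0.51, adjusted p = 0.0808) or Fabp4 (−0.52, adjusted p = 0.0537). The count was 169 without E12.5 replicate 1, 223 without E15.5 replicate 1, 272 without E15.5 replicate 2, 214 with stricter cell calls, 218 without centring and 190 by DESeq2, which gave 4805 genes no adjusted p.

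**Figure D4:**
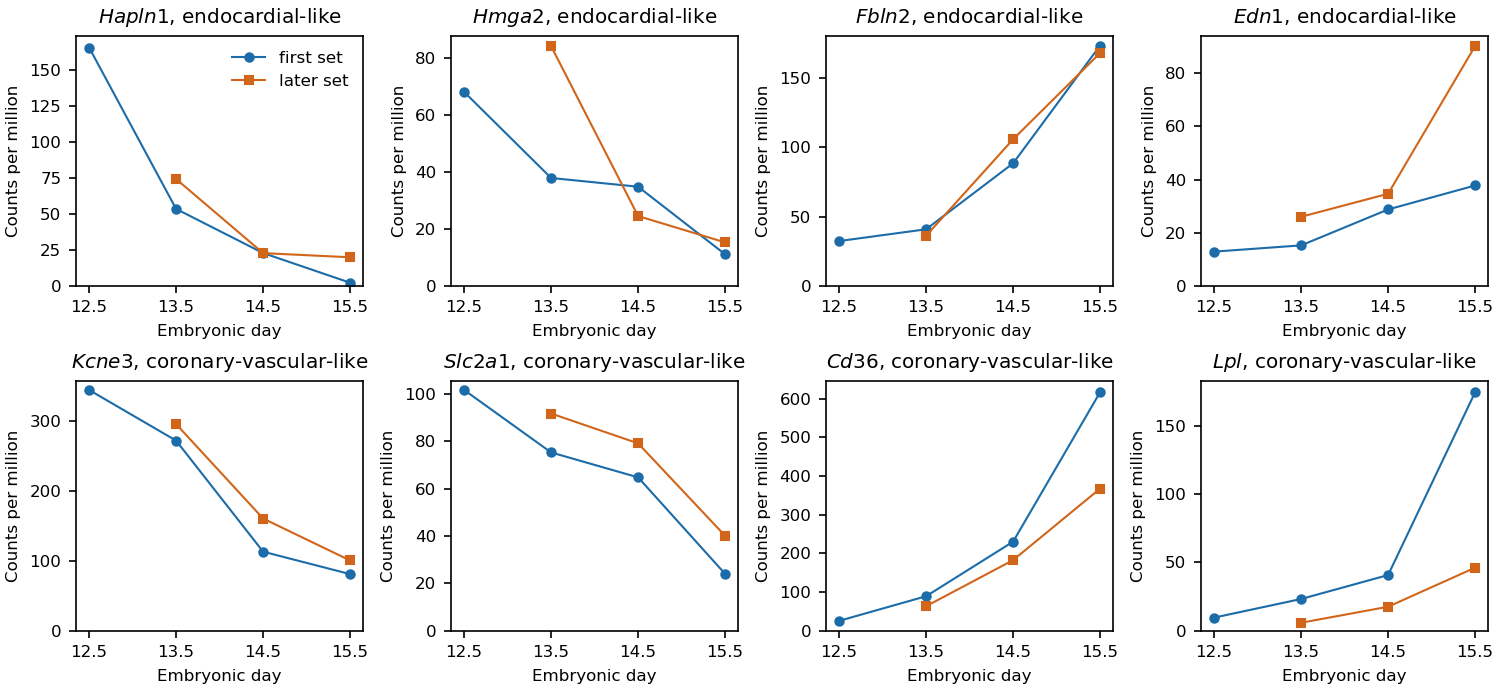
Level in CPM by embryonic day for Hapln1, Hmga2, Fbln2 and Edn1 in endocardial-like cells and for Kcne3, Slc2a1, Cd36 and Lpl in coronary-vascular-like cells, with a symbol per library and set. Hapln1 falls from 166 CPM at E12.5 to 2.15 and 19.8 CPM at E15.5, and Cd36 rises from 25.8 to 617 and 368 CPM.

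The transition named by the series was then compared between the classes. The mesenchymal effector list was higher and the lists of S phase and of G2 and M phase were lower in endocardial-like than in coronary-vascular-like cells of the same libraries. With an estimated correlation none of the 3 calls held (adjusted p = 0.0987, 0.245 and 0.245). Col5a1, a fibrillar collagen, was 3.60 log2 higher (SE 0.15, n = 7 pairs of sums; edgeR adjusted p = 7.48e-14; ENSMUSG00000026837, chr2:27886425-28039514), at a mean of 45.4 ± 24.5 CPM (SD) against 3.53 ± 2.09. Fn1 (3.67), Col3a1 (3.49) and Fbn1 (3.06) were higher too, while Sparc (−1.47) and Vim (−0.52) were lower. The EndMT regulators split: Zeb2, a repressor of epithelial genes, was 2.25 log2 higher in endocardial-like cells (SE 0.10, adjusted p = 1.92e-13; ENSMUSG00000026872, chr2:44983632-45117395), in 7 of 7 libraries. Foxc2 (2.79), Twist1 (1.60), Tbx20 (1.22) and Zeb1 (0.17) were higher as well, whereas Msx1 (−2.33), Hmga2 (−1.64), Tcf4 (−1.33), Snai2 (−1.24), Prrx2 (−0.91) and Tcf3 (−0.41) were lower.

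As lists, the mesenchymal effectors were higher in endocardial-like cells (12 of 21 members higher and 2 lower, the same counts adjusted over the list alone, median 1.47; camera adjusted p = 0.000205, and 0.0987 with an estimated correlation). The EndMT regulators were not called (5 of 12 higher and 6 lower, the same counts adjusted over the list alone, adjusted p = 0.634). Snai1 differed by 0.17 (adjusted p = 0.618) and Cdh2, the N-cadherin gene, by −0.13 (adjusted p = 0.543), a sign that turned without TMM factors, with stricter cell calls and without E14.5 replicate 2 (0.0073, 0.14 and 0.067). S phase genes were lower in 25 of 27 members (25 adjusted over the list alone, median −0.83; adjusted p = 2.35e-08, and 0.245 with an estimated correlation), with Fen1 at −1.22, Cdc45 at −1.65, Mcm3 at −0.85 and Cdc6 at −1.50. G2 and M phase genes were lower in 30 of 31 (31 adjusted over the list alone, median −1.11; adjusted p = 9.80e-10, and 0.245 with an estimated correlation), with Bub1 at −1.50, Cdk1 at −1.20, Cks2 at −0.92 and Ccnb1 at −1.53. In all, 7469 of 11264 genes differed between the classes, 3833 of them higher in endocardial-like cells; without TMM factors the median of all genes moved by 0.14 log2. Median UMIs were 10756 to 20786 per coronary-vascular-like cell and 7070 to 12340 per endocardial-like cell.

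Finally, the share of endocardial-like cells with RNA of any EndMT regulator was compared by stage, to see whether more cells carried it as vessels formed. After thinning to 3000 UMIs, 82.8% of endocardial-like cells had such a UMI at E12.5 (95% exact interval 79.3% to 85.9%). The shares were 84.8% and 82.9% at E13.5, 80.9% and 84.3% at E14.5, and 85.0% and 78.8% at E15.5. Hmga2 alone was found in 18.3% of endocardial-like cells at E12.5 and in 3.56% and 3% at E15.5, and Tcf4 in 30.9% at E12.5 and in 42.7% and 43.9% at E15.5, so the pooled share holds members that went opposite ways. Snai1, Snai2 and Twist1 were found in 0.241% to 2.41% of endocardial-like cells, against 13.7% to 23.9% for Snai1 and 15.1% to 22.7% for Snai2 in cushion mesenchymal-like cells. Twist1 was found in 40.2% of cushion mesenchymal-like cells at E12.5 and in 7.95% and 16.9% at E15.5.

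The logit slope of the share was −0.0252 ± 0.0669 per day (SE, n = 7; exact permutation p = 0.722). It was 0.0181 in the first set, −0.134 in the later set and 0.0263 without E15.5 replicate 2. It was −0.0968 (exact p = 0.0694) when thinned to 2000 UMIs, −0.140 (exact p = 0.0972) without centring and −0.0733 (exact p = 0.0833) with a mitochondrial limit of 10%. Coronary-vascular-like cells had shares of 75.8% to 88.3% (slope 0.174 ± 0.103, exact p = 0.167) and cardiomyocyte-like cells of 59.1% to 74.1% (exact p = 0.236). Erythroid-like cells, thinned to the same depth, had shares of 2.8% to 12.7%, with a slope of −0.253 ± 0.0628 (exact p = 0.0278), and no share was computed for barcodes without a cell.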

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

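The tests of free eGFP RNA, of a mixture of marked and unmarked cells, of free cardiomyocyte RNA, of lung cells, of sex and of other stage orders were chosen only after the results they bear on were seen.

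A difference between classes singled out the slopes of 443 genes, which differed between coronary-vascular-like and endocardial-like cells in the joint edgeR fit of 7 libraries per class. Among the named genes, the coronary-vascular-like slope minus the endocardial-like slope was 1.66 log2 per day for Tspan7, 1.19 for Ly6e, 1.07 for Lgals9, 0.85 for Timp2 and 0.83 for Rgcc. It was −1.10 for Npr3, −0.91 for Egln3, −0.91 for Igfbp3, −0.85 for Pdgfb and −0.76 for Sat1.

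A signal in data no comparison used was the eGFP entry of the first set, for which the labels name no reporter. At least 1 eGFP UMI was found in 51.3%, 73.3%, 86.5% and 81.0% of endothelial-like cells, in order of stage from E12.5 to E15.5. Free eGFP RNA is argued against as the source, since endocardial-like cells had at least 19.6 times the eGFP level of cardiomyocyte-like cells in each of the 4 libraries. The coronary-vascular-like cells fell short of the Poisson share for their depth by at least 10.8 percentage points more than the endocardial-like cells did, in each of the 4 libraries, so this class may mix marked and unmarked cells, but cluster 4 at E15.5 fell short by 3.49 points against 3.21 in endocardial-like cells and cluster 8 at E14.5 by 6.40 against 5.55. Uneven expression among marked cells stays open, as cushion mesenchymal-like cells fell short by up to 25.4 points, and neither a biological explanation nor a change with stage was tested.

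Genes of cardiomyocytes rose in both endothelial classes, with a median slope of 0.29 log2 per day over the 13 listed genes in endocardial-like and 0.46 in coronary-vascular-like sums in the edgeR fits (0.45 in the voom fit behind the list test). Doublets with cardiomyocytes are argued against, because the slope of the median over endocardial-like cells was 1.05 times the slope of the mean, so the rise did not sit in few cells. Free cardiomyocyte RNA may account for the rise: the same 13 genes had a median slope of 0.483 in leukocyte-like sums. All of them were tested in both classes and none was held by another gene list. The list was not called in valve endocardial-like cells (median 0.11, adjusted p = 0.247) or inside coronary-vascular-like cluster 8 (median −0.14, adjusted p = 0.454). Both fits held fewer libraries, because some had too few cells. The valve endocardial-like fit lacked E15.5 replicate 1, and the cluster 8 fit lacked E12.5 replicate 1 and E13.5 replicate 1. They therefore cannot decide against free RNA. Without E15.5 replicate 1 the list stayed called in endocardial-like cells with the preset correlation. In barcodes without a cell of the later set, Ckm stood at 174, 896 and 1257 CPM at E13.5, E14.5 and E15.5, against 7.67, 44.6 and 53.5 CPM in endocardial-like cells, and the abundant gene Tnnt2 stood at 5552, 9825 and 7603 CPM. A further rise within endothelial cells stays open, the labels name no sort that would remove cardiomyocytes, and a biological explanation by stage was not tested apart from the free RNA.

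Genes that changed with stage in coronary-vascular-like cells were weighed because the class moved from cluster 4 to cluster 8 and because 1 E15.5 library held lung-like cells. Each of 3 explanations is argued against as the whole cause, since the median slope of the called genes, in the direction of the call, was 0.846 times its size inside cluster 4 alone, 0.948 times without E15.5 replicate 1 and 1.05 times with the Xist level as a term. The genes were called on the same cells and libraries, which favours ratios near 1. The ratios therefore do not measure how much each explanation contributed, and a part played by each stays open. Of 60 stage orders drawn within sets, 1, the real one, gave as many called genes (1436, against 680 for the highest other order). For endocardial-like cells 1 of 60 did (912, against 182). Not all orders were drawn. The order with the days reversed in both sets, which must give the same counts with the signs turned, was not among them. The share is therefore not exact, and the draw cannot exclude chance. Inside cluster 4, 1385 of 1391 called genes tested kept their direction, and inside cluster 8, in the 5 libraries with at least 20 of its cells, 1034 of 1122. A change of vessel-like cells with stage may account for the pattern, as a hypothesis found and tested on the same data, and handling that differed by stage stays open.

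A signal in cells outside the comparisons was a group of 238 epithelial-like cells in E15.5 replicate 1, led by Sftpc and Scgb3a2, genes of lung epithelium. They made up 5.29% of its cells (95% exact interval 4.65% to 5.98%), with 8 such cells in E13.5 replicate 1 and 0 in the other 5 libraries, which allows shares of up to 0.0408% to 0.0801%.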

How the results depend on the processing

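The alternatives with an Xist term, the gene and list fits within each set, edgeR without TMM factors and the fits without both E12.5 replicate 1 and E15.5 replicate 1 were chosen after seeing the data. For endocardial-like cells, 912 became 235 without centring, 61 without the set term, 346 with stage as a factor, 164 with an Xist term, 109 in the later set alone and 51 without both E12.5 replicate 1 and E15.5 replicate 1. Leaving out 1 library each gave 191 to 1025, with 227 without E12.5 replicate 1, 191 without E15.5 replicate 1 and 542 without E13.5 replicate 2. For coronary-vascular-like cells, 1436 became 565 without the set term, 866 by DESeq2, 784 with stage as a factor, 632 with an Xist term, 383 in the later set alone and 205 without both libraries. Leaving out 1 library each gave 451 to 1525, with 647 without E12.5 replicate 1 and 451 without E15.5 replicate 1. For the slope difference, 443 became 214 with stricter cell calls, 218 without centring and 190 by DESeq2. Leaving out 1 library each gave 169 to 456, with 169 without E12.5 replicate 1, 223 without E15.5 replicate 1 and 272 without E15.5 replicate 2. Fits with libraries left out or within a set hold fewer samples; for the other changes the cause was not tested. Of the 912 endocardial-like genes, 65 were called in the later set alone with the same direction and 3 with the opposite; of the 1436, 299 and 8. Lists called were 15, 11 and 3 for the endocardial-like, coronary-vascular-like and class comparisons with the preset correlation and 0, 4 and 0 with an estimated one; leaving out 1 library each gave 14 to 16, 10 to 13, and 3 each time with the preset correlation, and for both slope comparisons 0 each time with an estimated one. No named stage slope gene turned direction, an outcome that the naming rule fixed for the fits within each set. Over the alternatives other than single libraries left out, 278 values for endocardial-like genes stayed past the threshold and 42 did not, and 291 and 29 did for coronary-vascular-like genes. Cdh2, not called between classes, turned to 0.14 with stricter cell calls and 0.0073 without TMM factors, and lay between −0.25 and 0.067 with 1 library left out (0.067 without E14.5 replicate 2), for which the cause was not tested. The endothelial-like share slope turned to 0.0121 in the later set and 0.0165 with a mitochondrial limit of 10%, and lay between −0.200 and −0.0705 with 1 library left out. The coronary-vascular-like share slope was 0.488 without the set term, where its adjusted p of 0.00952 passed, and 0.453 to 0.526 with 1 library left out. The EndMT regulator share slope of −0.0252 was −0.0968 when thinned to 2000 UMIs, −0.0966 without thinning, −0.0837 with doublets kept, −0.140 without centring, −0.0733 with a mitochondrial limit of 10% and −0.134 in the later set, none of them past the threshold. It turned to 0.0181 in the first set, and lay between −0.100 and 0.0263 with 1 library left out, the latter without E15.5 replicate 2; the cause was not tested. Within a set alone, the orders allow no exact p below 0.0833 in the first and 0.333 in the later set, so no share slope could pass there. A minimum of 2000 UMIs removed no cell, so it tested nothing. Where a stage was left with 1 library in all, it was assumed to vary like the others. Between stages no paired analysis was possible because the replicate numbers name a set, which was a term of the fits, and no shared animal; the classes were compared within libraries. Snai1, Snai2 and Twist1 had UMIs in few endocardial-like cells, so their values there rest on few counts.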

Other observations

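The fits of the other cell classes were chosen only after the data were seen, with the model used for the endothelial classes.

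The mesenchymal effector list rose with stage in valve endocardial-like (camera adjusted p = 0.003, and 0.406 with an estimated correlation), cushion mesenchymal-like (0.00846, and 0.336) and fibroblast-like cells (3.01e-07, and 0.128). It fell in cardiomyocyte-like cells (0.00355, and 0.482) and was not called in epicardial-like (0.275) and leukocyte-like cells (0.474). The fibroblast markers, which share members with it, rose in valve endocardial-like (median 0.54, adjusted p = 2.11e-10, and 0.324 with an estimated correlation) and cushion mesenchymal-like cells (median 0.27, 2.07e-09, and 0.307). They also rose in fibroblast-like (6.81e-10, and 0.128) and epicardial-like cells (3.78e-05, and 0.286), and were not called in cardiomyocyte-like cells (0.977). The basement membrane and matrix list rose in fibroblast-like (3.81e-06, and 0.247 with an estimated correlation), valve endocardial-like (0.0484, and 0.491) and epicardial-like cells (0.0271, and 0.459). It was not called in cushion mesenchymal-like (0.85), cardiomyocyte-like (0.789) and leukocyte-like cells (0.474). In valve endocardial-like cells 44 of 9412 genes changed (edgeR, 38 up and 6 down, n = 6, since E15.5 replicate 1 held 12 such cells, under the limit of 20), among them Postn, the valve matrix protein periostin (0.99 log2 per day, SE 0.08, adjusted p = 1.75e-06), and Mgp (0.77), with Cdo1 (−0.74) and Nts (−0.38) down. In cushion mesenchymal-like cells 675 of 11464 genes changed, 423 up and 252 down. Dcn, a small proteoglycan of collagen fibrils, rose by 1.42 (SE 0.10, adjusted p = 0.000155) and Abi3bp by 2.81, while Hmga2 (−0.98), the myostatin gene Mstn (−0.85) and Sox11 (−0.63) fell. In fibroblast-like cells 473 of 11785 genes changed, 347 up and 126 down, with Dpt (2.53), Aspn (1.35) and Col15a1 (1.25) up and Hmga2 (−1.06) and Meis2 (−0.63) down. Markers of mural cells rose as a list in this class (median 1.10; camera adjusted p = 9.27e-11, and 0.128 with an estimated correlation), with the pericyte genes Kcnj8 (1.12) and Ndufa4l2 (1.23). In epicardial-like cells 695 of 11327 genes changed, with Mt1 (1.18) and Igfbp6 (1.06) up and Hmga2 (−1.08) and Cxcl12 (−0.62) down. Markers of cardiomyocytes rose as a list in cushion mesenchymal-like cells (camera adjusted p = 9.255e-05, and 0.336 with an estimated correlation). They rose in fibroblast-like (0.00108, and 0.413) and epicardial-like cells (0.0155, and 0.5) too, and were not called in valve endocardial-like cells (0.247). Ckm rose by 1.76, 1.60 and 1.60 in cushion mesenchymal-like, fibroblast-like and epicardial-like cells.

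In cardiomyocyte-like cells, of 13463 genes, 1674 changed (edgeR, 1032 up and 642 down, n = 7). Ckm rose by 1.52 (SE 0.15, adjusted p = 0.00298), Cox8b, a subunit of cytochrome oxidase, by 1.21, the calcium store protein gene Casq2 by 1.09 and Acsl1, which activates fatty acids, by 0.97. Krt19 (−0.89), Cdkn1c (−0.67) and Ccnd1 (−0.46) fell. The fatty acid list rose (median 0.40, camera adjusted p = 2.25e-09, and 0.233 with an estimated correlation), as did oxidative phosphorylation (median 0.18, adjusted p = 1.80e-08, and 0.482 with an estimated correlation), while S phase fell (median −0.17, adjusted p = 2.66e-07, and 0.56 with an estimated correlation). The G2 and M phase list was not called (median −0.027, camera adjusted p = 0.3615). In leukocyte-like cells 288 of 9004 genes changed, 200 up and 88 down.

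Several groups of endothelial-like cells stayed unnamed. Cluster 15, led by Gja5, Kcnj8 and Hey1, genes of arterial endothelium among them, held 0, 3, 8 and 25 cells of the first set by stage and 0, 15 and 20 of the later set. Cluster 6, led by Aqp8 and Pdgfra, held 406 cells, cluster 9, led by haemoglobin genes, 192, cluster 13 held 105, and cluster 14, led by cardiomyocyte genes, 75. Lymphatic-like cells made up 0% to 1.70% of endothelial-like cells. Over all kept cells Ddx3y, a Y-linked gene, had 2570 and 2399 UMIs at E14.5 and E15.5 in the first set and 0 at E14.5 in the later set. The eGFP level in the first set was 74.8, 135, 255 and 264 CPM in cushion mesenchymal-like cells by stage, and 2.18 to 4.48 CPM in epicardial-like cells.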
